A study of Vibrio parahaemolyticus RIMD 2210633 with 24 samples.

How the data were processed

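The samples were cultures of Vibrio parahaemolyticus, a marine bacterium with a pair of chromosomes, profiled on 24 one-colour Agilent arrays. Per the labels' protocols, exponential cultures were grown for 4 h and early stationary cultures for 7 h at 37 °C in alkaline peptone water. Cells in the viable but non-culturable (VBNC) state, which are alive but form no colonies, came from washed stationary cells held without shaking at 4 °C for over 40 days. Temperature, time and handling therefore changed together with the VBNC state. Per the labels' protocols, total RNA was amplified with MultiStart primers and labelled with Cy3. The design text in the labels speaks of 8 biological replicates per state.

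The scanner files hold the intensity of each spot on a linear scale, with background-subtracted processed signals and quality flags, per the file headers. They were made with Agilent Feature Extraction 10.5.1.1 and its protocol GE1_107_Sep09, per the file headers. Each array held 15199 probes of 60 bases for 4820 genes, of which 3073 lie on chromosome 1 (VP tags) and 1747 on chromosome 2 (VPA tags). A second, deposited table holds log2 values of the same arrays. Each of its 24 columns ranked the probes as its own array did (Spearman rho of 1 across probes), with Pearson correlations from 0.984 to 0.999 with the log2 intensities. All its columns share a median of 5.45, so its values were brought to a common scale and were not centred per gene. The tool behind that step is not given in the sources used here. Between 0 and 388 of its values were empty per array.

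From the intensity files, log2 of the processed signal was taken and each array's 75th percentile of it was subtracted. A level of 0 is therefore the 75th percentile of the array. Control spots and spots marked as non-uniform or as population outliers (0 to 27 per array) were left out, and no spot was saturated. The mean log2 value over a gene's probes was used. A gene was tested if at least 1 of its probes was well above background on at least 6 of the 8 arrays of at least 1 group. This kept 4494 genes and left out 326, of which 133 lie in 1 region of chromosome 2 (VPA0910 to VPA1043). Probes of a gene changed in opposite directions in 8 of the 95 gene and comparison pairs named by the rule below, none of which passed the test.

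Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit over all 24 arrays with a term for group only, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene passed at an adjusted p below 0.05 and at least a 2-fold change. Values after ± are standard errors of the log2 fold change unless marked SD. Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with the correlation estimated from the arrays was the alternative. Of 32 lists, 31 had at least 3 measured genes and were tested; the list of ribosomal and transfer RNA was not, since the array names no such genes. Within the 93 pairs of list and comparison, the counts of passing members adjusted over the list alone differed from those adjusted over all genes in 4. These were 28 in place of 27 falls in the capsule list for VBNC against early stationary cells. Between the growth phases they were 0 in place of 1 rise in type IV pili, 1 in place of 3 falls in iron acquisition and 1 in place of 2 falls in compatible solutes.

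The lists, the comparisons, the tests, most alternatives and the rule for named genes were fixed before the data were examined. Since the array carries no gene symbols, symbols in the lists were matched to words of the product names, and enzyme names for glycolysis, fatty acid synthesis and fatty acid degradation were added after the annotation was seen and before samples were compared. Genes were named in each comparison if they passed, had all 8 arrays of a group above the 8 of the other, and had a product name other than hypothetical, uncharacterized or unknown. Of these, the 4 largest rises and 4 largest falls were taken, and the 2 largest changes in list direction from each of the 8 lists with the smallest p among lists past the test. A "largest" change means largest among genes that meet this rule. Genes named by it were well above background on at least 4 of 8 arrays of each group unless stated otherwise. Always named were 8 fixed genes (rpoS, toxR, opaR, relA, recA, ftsZ, tlh and tdhA). Where no probe of a gene was well above background on any array of a group, the change is given as at least N-fold. That bound sets the bright group's mean against the dim group's mean of, per array, the higher of the gene's own value and the lowest signal well above background.

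The arrays came from 3 slides of 8, each scanned at its own time, and each slide held all 3 groups. Comparisons were therefore repeated within each slide and with slide as a block. Other alternatives were quantile normalization, the array median, no scaling, a trimmed mean (20% from each end) of genes well above background on all arrays, normexp background correction (offset 50), the deposited log2 values, other filters, probe summaries, tests and thresholds, and the replicate number as a block. The normexp offset is added to every signal and so shrinks the log2 changes of dim genes by construction. Added after seeing the data were the mean of each group's arrays on each slide (3 values per group), a random block for those sets, and fits without VBNC replicates 1 and 2, without exponential replicate 6 or without exponential replicate 2.

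The fit was tested on simulated data for VBNC against exponential cells, with 4494 genes of which 200 were changed. It recovered 42.9% of changes of 1 log2 unit, which lie at the 2-fold minimum. Recovery was 88.6% at 1.5, 96.9% at 2 and 99.8% at 3 log2 units, with a mean of 4.30 unchanged genes called. The simulated arrays were independent of each other, as were the simulated genes, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Positions are those of the array annotation, whose genome build is not given in the sources used here.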

Results

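Gene expression was measured in Vibrio parahaemolyticus in 3 states: exponential growth, early stationary phase and the VBNC state. Each state was represented by 8 arrays. The 75th percentile of the processed signal lay between 24.9 and 212 on exponential arrays, between 52.6 and 81.6 on early stationary arrays and between 44.6 and 542 on VBNC arrays. VBNC replicates 1 and 2, both on slide 1, were dim at 50.0 and 44.6, and exponential replicate 6 was the dimmest array at 24.9. Exponential replicate 2 had the highest share of probes well above background, 95.0%. The share of probes well above background was 68.5% ± 15.0 (SD, n = 8) in exponential, 58.7% ± 6.39 (SD, n = 8) in early stationary and 82.7% ± 16.5 (SD, n = 8) in VBNC cells.

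Arrays of a group that shared a slide were more alike than arrays of that group on different slides. The median root mean square log2 difference between VBNC arrays was 0.263 within slides and 0.913 across slides. It was 0.380 and 0.756 for early stationary arrays, and 0.847 and 1.25 for exponential arrays. The design text speaks of 8 biological replicates per state, but the labels do not say which arrays came from separate cultures. The p-values and standard errors therefore measure the spread between these arrays, which may in part be technical, and treat the 8 as independent. Since arrays that share a slide are alike, the standard errors may be too small. The exponential arrays of slide 1 lay near the early stationary ones, with a mean correlation across genes of 0.949, against 0.879 on slide 2 and 0.853 on slide 3.

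**Figure D1:**
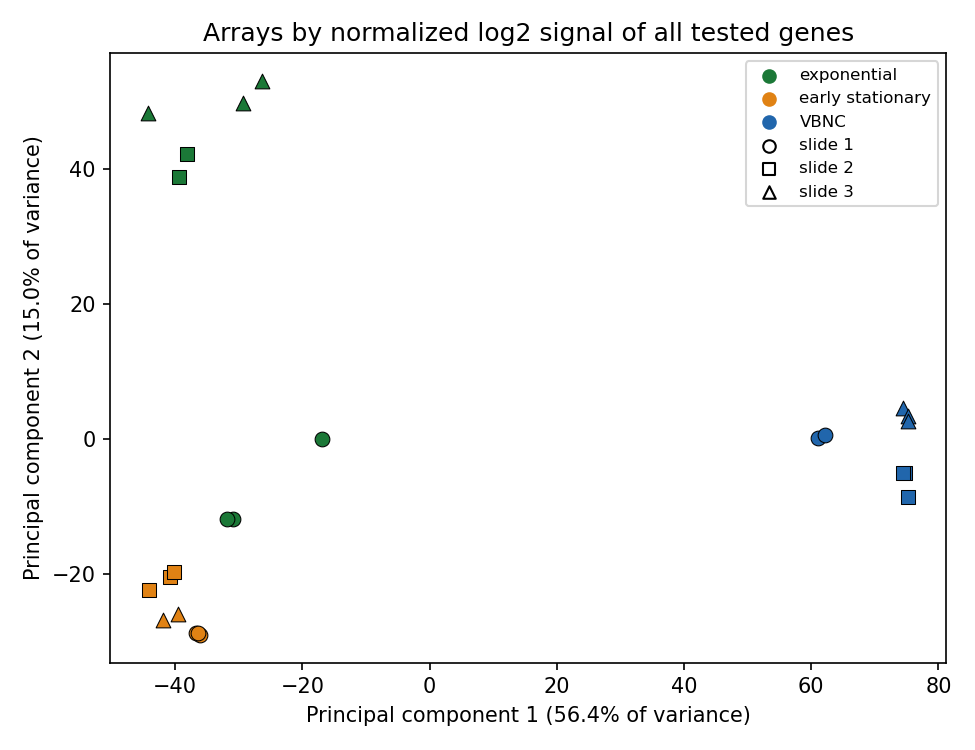
Principal components of the normalized log2 signal of the 4494 tested genes, with component 1 (56.4% of the variance) on the x axis and component 2 (15.0%) on the y axis. Points are the 24 arrays, coloured by group and shaped by slide; all 8 VBNC arrays lie apart on component 1, and the exponential arrays of slide 1 lie near the early stationary arrays.

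The first comparison asked how VBNC cells differed from exponentially growing cells. Slide medians of a list are given for slides 1, 2 and 3 in that order. The respiratory chain list did not pass (7 of 20 genes rose and 8 fell, median 0.16, adjusted p = 0.58, and adjusted p = 0.84 with an estimated correlation). The largest fall with a product name was in VP0847, the E1 component of 2-oxoglutarate dehydrogenase of the tricarboxylic acid (TCA) cycle (chromosome 1, 877572 to 880397). It fell 66.4-fold, from 6.24 ± 1.03 (SD, n = 8) to 0.19 ± 0.87 (SD, n = 8), a log2 change of -6.05 ± 0.37 (adjusted p = 1.6e-13). In the list of the TCA cycle and glyoxylate shunt, 9 of 14 measured genes fell and 2 rose (list median -3.22, adjusted p = 9.1e-04, and adjusted p = 0.25 with an estimated correlation, slide medians -3.04, -3.16 and -3.36). VP0847 was not matched to this list. Of its members, citrate synthase (VP0842) changed by -4.31 ± 0.27 and class I fumarate hydratase (VP1873) by -4.28 ± 0.32. The 2 that rose, named after their values were seen, were malate synthase A (VP0583, 2.66 ± 0.21) and isocitrate lyase (VP0584, 1.30 ± 0.30), the enzymes of the glyoxylate shunt. All 8 measured genes of the ATP synthase fell (median -3.05, adjusted p = 4.7e-05, and adjusted p = 0.25 with an estimated correlation, slide medians -1.88, -3.58 and -3.55), with log2 changes of -3.58 ± 0.27 in the F0 subunit A (VP3075) and -3.25 ± 0.31 in the F1 gamma subunit (VP3070).

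Of 55 ribosomal protein genes, 29 fell and 4 rose in VBNC against exponential cells (median -1.09, adjusted p = 3.6e-04, and adjusted p = 0.34 with an estimated correlation, slide medians -0.50, -1.42 and -0.97). S9 (VP0439) changed by -2.05 ± 0.25 and S21 (VP0407) by -1.56 ± 0.20, with -0.41 for S21 on slide 1. Translation factors (6 of 13 fell, 1 rose, adjusted p = 0.040, and adjusted p = 0.25 with an estimated correlation, slide medians -0.67, -1.27 and -1.15) had a median of -0.89. Aminoacyl-tRNA synthetases (8 of 28 fell, 2 rose, adjusted p = 0.027, and adjusted p = 0.25 with an estimated correlation, slide medians -0.39, -0.63 and -0.75) had a median of -0.66. Both medians were above 0 only with no scaling among the scalings tried. All 3 measured genes of ribosome hibernation, whose products store inactive ribosomes, fell (median -2.62, adjusted p = 0.024, and adjusted p = 0.25 with an estimated correlation, slide medians -2.55, -1.77 and -2.93). In glycolysis 8 of 13 genes fell and 1 rose (adjusted p = 0.037, and adjusted p = 0.53 with an estimated correlation, slide medians 0.59, -2.04 and -2.21), so the list median was above 0 on slide 1. In fatty acid synthesis 7 of 16 fell and 1 rose (median -0.81, above 0 with no scaling; adjusted p = 0.029, and adjusted p = 0.46 with an estimated correlation, slide medians -0.79, -0.99 and -0.99).

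In the capsule and exopolysaccharide list 15 of 29 genes fell and 1 rose (median -1.08, adjusted p = 0.0078, and adjusted p = 0.53 with an estimated correlation, slide medians -1.68, -0.49 and -0.51). Glucose-1-phosphate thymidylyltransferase (VP0223) changed by -3.82 ± 0.36 and dTDP-4-dehydrorhamnose 3,5-epimerase (VP0229) by -2.62 ± 0.33; both act in dTDP-rhamnose synthesis, and they were well above background on 7 and 6 of 8 VBNC arrays. In type III secretion system 2, 13 of 43 genes fell and 4 rose (median -0.64, above 0 with no scaling; adjusted p = 0.031, and adjusted p = 0.75 with an estimated correlation, slide medians -0.34, -0.18 and -1.22). Outside the lists, ribose transporter genes VPA1087 (63.1-fold) and VPA1086 (48.4-fold) and a putative sugar phosphotransferase component (VPA0230, 47.8-fold) showed the next largest falls.

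Among rises against exponential cells, VP1890, annotated as a putative VacB/RNase virulence-associated protein (chromosome 1, 1971918 to 1974143), came first. It was 82.1-fold higher, at 2.43 ± 0.56 (SD, n = 8) against -3.93 ± 0.78 (SD, n = 8), a log2 change of 6.36 ± 0.29 (adjusted p = 3.9e-16). It was well above background on 5 of 8 exponential arrays. A putative tyrosine transporter (VPA0509, 44.3-fold), an ABC transporter permease (VPA0134, 43.8-fold) and a putative multidrug resistance protein (VP0060, 43.4-fold) followed. In phosphate uptake, 10 of 11 genes rose and none fell (median 2.53, adjusted p = 1.9e-04, and adjusted p = 0.25 with an estimated correlation, slide medians 2.25, 2.37 and 2.58), including the permease genes VP0574 (4.21 ± 0.28) and VPA1459 (3.23 ± 0.27), the latter well above background on 2 of 8 exponential arrays. Of 29 type IV pilus genes, 20 rose and 2 fell (median 1.77, adjusted p = 2.9e-05, and adjusted p = 0.25 with an estimated correlation, slide medians 1.51, 2.29 and 1.96), including mshO (VP2694, 4.00 ± 0.35) and pilP (VP2747, 3.89 ± 0.30). In SOS and DNA repair 10 of 19 genes rose and 1 fell (median 1.05, adjusted p = 0.017, and adjusted p = 0.25 with an estimated correlation, slide medians 0.80, 0.95 and 1.25). The repair genes recN (VP0648) and recO (VP2570) changed by 4.38 ± 0.19 and 2.97 ± 0.20. In the superintegron, an array of gene cassettes, 43 of 78 genes rose and 2 fell (median 1.15, adjusted p = 2.5e-06, and adjusted p = 0.40 with an estimated correlation, slide medians 0.34, 1.66 and 1.46), among them VP1816 (2.36 ± 0.25, a putative Hit protein) and VP1821 (1.57 ± 0.22, a putative YefM protein). VBNC arrays were brighter on slides 2 and 3, and the superintegron median was 0.12 with normexp, where the median of all genes was -0.40. Other medians over 1.5 times smaller with normexp were 0.57 for phosphate uptake, 0.82 for type IV pili, 0.19 for iron acquisition and -0.55 for translation factors. In iron acquisition 10 of 28 genes rose and none fell (adjusted p = 0.020, and adjusted p = 0.53 with an estimated correlation, slide medians -0.16, 1.25 and 1.56), so the list median was below 0 on slide 1.

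Of the fixed genes, relA (VP2564, a GTP pyrophosphokinase of the stringent response) passed, with -1.13 ± 0.20 (adjusted p = 2.0e-05), and its values on slides 1, 2 and 3 were -0.16, -1.88 and -1.28. The others did not pass, with values of 0.70 ± 0.17 for rpoS (VP2553, the general stress sigma factor), -0.91 ± 0.25 for toxR (VP0820, a virulence regulator), -0.31 ± 0.37 for opaR (VP2516, a quorum-sensing regulator), 0.21 ± 0.37 for recA (VP2550) and -0.62 ± 0.15 for ftsZ (VP0464, of the division ring). For the haemolysin genes tlh (VPA0226) and tdhA (VPA1314) the values were -0.67 ± 0.24 and 0.00 ± 0.33. Among the genes that did not pass, rpoS, toxR, ftsZ and tlh missed only the 2-fold minimum (limma adjusted p = 5.9e-04, 0.0026, 5.5e-04 and 0.015). A near-identical copy of tdhA may share its signal, so its value is uncertain.

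The VBNC cells also differed from the others in temperature, time and handling, which cannot be separated from their state. In total 1125 genes were higher and 1008 lower in VBNC than in exponential cells among 4494 tested (limma). The counts were 1020 and 993 within slide 1, 1494 and 1071 within slide 2, and 1155 and 1276 within slide 3. With slide as a block they were 1137 and 1014. Of the passing genes 91.2% had the same sign on all slides, which is in part built in, since they were chosen on these same slides. Within slide 1 alone, 757 of the 1125 higher and 665 of the 1008 lower genes passed in the same direction. The split moved to 1425 higher and 737 lower with the trimmed mean, 393 and 613 with normexp, and 1994 and 276 with no scaling. With quantile normalization these lists no longer passed, though their medians were close to those above: translation factors (-0.81 against -0.89, adjusted p = 0.095), aminoacyl-tRNA synthetases (-0.56 against -0.66, adjusted p = 0.054), glycolysis (-1.43 against -1.35, adjusted p = 0.056) and fatty acid synthesis (-0.86 against -0.81, adjusted p = 0.091). The median of the ribosomal proteins was -0.60 with quantile normalization and -0.58 with the deposited values, against -1.09 above. With the trimmed mean, medians over 1.5 times apart from those above were -0.58 for translation factors, -0.35 for aminoacyl-tRNA synthetases, -0.50 for fatty acid synthesis and -0.33 for type III secretion system 2. No scaling moved the median of all genes by 1.06. Lower lists then had medians of -0.03 for ribosomal proteins, 0.17 for translation factors, 0.40 for aminoacyl-tRNA synthetases, -1.56 for ribosome hibernation, -1.996 for the ATP synthase, -0.29 for glycolysis, 0.25 for fatty acid synthesis, 0.42 for type III secretion system 2 and -0.02 for the capsule list. Medians of the higher lists were 2.11 for SOS and DNA repair, 2.83 for type IV pili, 1.78 for iron acquisition and 2.21 for the superintegron.

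**Figure D2:**
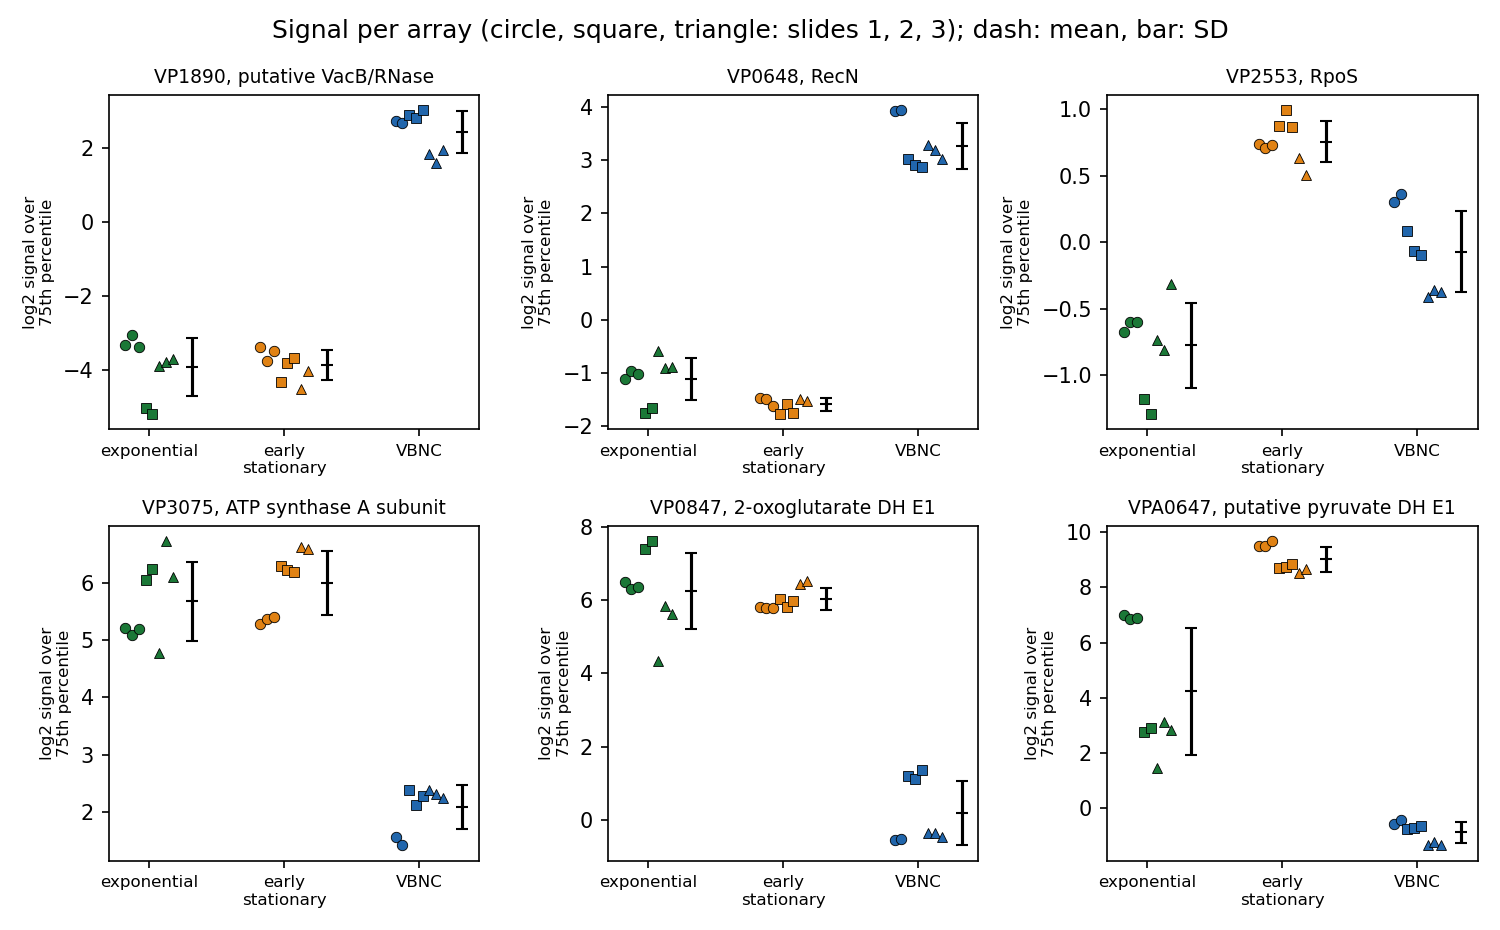
Normalized log2 signal over the array's 75th percentile for 6 named genes on the 24 arrays, in exponential, early stationary and VBNC cells. Points are arrays shaped by slide, dashes group means and bars SDs (n = 8). VP1890 and recN (VP0648) lie higher and VP3075, VP0847 and VPA0647 lower on all 8 VBNC arrays than on any other array, and VPA0647 splits by slide in exponential cells.

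The second comparison set VBNC cells against early stationary cells. The largest falls were in adjacent genes annotated as putative pyruvate dehydrogenase E1 components. VPA0647 (chromosome 2, 651901 to 652995) was 949.7-fold lower, from 9.01 ± 0.45 (SD, n = 8) to -0.88 ± 0.36 (SD, n = 8), a log2 change of -9.89 ± 0.62 (adjusted p = 1.6e-13), and VPA0646 was 247-fold lower. Azurin (VPA1428), a copper protein of electron transfer, and the outer membrane protein OmpW (VPA0096) were 105-fold and 95.6-fold lower. In the capsule and exopolysaccharide list 27 of 29 genes fell and 1 rose (median -2.12, adjusted p = 6.4e-08, and adjusted p = 0.25 with an estimated correlation, slide medians -2.23, -2.003 and -2.44), with VP0223 at -4.82 ± 0.36 and VP0229 at -3.36 ± 0.33. Of 43 genes of type III secretion system 2, 24 fell and 1 rose (median -1.12, above 0 with no scaling; adjusted p = 7.9e-05, and adjusted p = 0.42 with an estimated correlation, slide medians -0.22, -1.25 and -1.80). The putative ATPase gene yscN (VPA1338) changed by -3.08 ± 0.25 and the EscC gene (VPA1339) by -2.89 ± 0.28.

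Against early stationary cells the respiratory chain list (4 of 20 rose, 9 fell, median -0.49, adjusted p = 0.066, and adjusted p = 0.44 with an estimated correlation) and glycolysis (3 of 13 rose, 4 fell, median -0.07, adjusted p = 0.35, and adjusted p = 0.72 with an estimated correlation) did not pass. All 8 ATP synthase genes fell (median -2.95, adjusted p = 8.7e-05, and adjusted p = 0.33 with an estimated correlation, slide medians -1.90, -3.59 and -3.40), with VP3075 at -3.90 ± 0.27 and the F0 subunit C gene VP3074 at -3.33 ± 0.26. In the TCA cycle and glyoxylate shunt 10 of 14 genes fell and 2 rose (median -3.08, adjusted p = 5.0e-04, and adjusted p = 0.25 with an estimated correlation, slide medians -2.64, -3.03 and -3.20). The succinate dehydrogenase genes VP0843 and VP0845 changed by -3.79 ± 0.20 and -3.46 ± 0.19, and the rises were again VP0583 (2.53) and VP0584 (1.43). Of the ribosomal protein genes, 32 of 55 fell and 5 rose (median -1.14, above 0 with no scaling; adjusted p = 1.7e-04, and adjusted p = 0.38 with an estimated correlation, slide medians -0.66, -0.92 and -1.45), including L7/L12 (VP2923, -3.19 ± 0.44) and L23 (VP0259, -2.72 ± 0.45). All 3 ribosome hibernation genes fell (median -3.80, adjusted p = 0.0090, and adjusted p = 0.25 with an estimated correlation, slide medians -2.09, -4.52 and -4.32). Fatty acid degradation (10 of 19 fell, 1 rose, adjusted p = 0.0019, and adjusted p = 0.39 with an estimated correlation, slide medians -0.95, -0.85 and -2.19) had a median of -1.08. Chaperones and proteases (13 of 28 fell, 5 rose, adjusted p = 0.034, and adjusted p = 0.42 with an estimated correlation, slide medians -0.61, -1.36 and -0.96) had a median of -0.80. Both medians were above 0 with no scaling.

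VP1890 again led the rises (79.3-fold, 6.31 ± 0.29, adjusted p = 5.4e-16), with 4 of 8 early stationary arrays well above background. A putative multidrug efflux protein (VPA0471) rose 43.2-fold and an O-methyltransferase-related gene (VP2944) 40.4-fold. The putative type III secretion gene VP1665, not well above background on any early stationary array, was at least 12.1-fold higher in VBNC cells (adjusted p = 1.2e-13). In SOS and DNA repair 12 of 19 genes rose and none fell (median 1.64, adjusted p = 6.6e-04, and adjusted p = 0.25 with an estimated correlation, slide medians 1.15, 1.65 and 2.11). Among them were recN (VP0648, 4.85 ± 0.19) and lexA (VP2945, the SOS repressor, 3.67 ± 0.28). Phosphate uptake (10 of 11 rose, none fell, median 2.39, adjusted p = 8.0e-04, and adjusted p = 0.25 with an estimated correlation, slide medians 2.14, 1.86 and 3.10) and type IV pili (20 of 29 rose, none fell, median 1.68, adjusted p = 8.7e-05, and adjusted p = 0.25 with an estimated correlation, slide medians 1.86, 1.66 and 1.22) rose as they did against exponential cells. The pilus genes pilP (VP2747) and mshD (VP2695) changed by 4.26 ± 0.30 and 3.64 ± 0.22. In the superintegron 52 of 78 genes rose and none fell (median 1.44, -0.08 with normexp; adjusted p = 4.2e-07, and adjusted p = 0.39 with an estimated correlation, slide medians 1.03, 1.71 and 1.25), including VP1816 (2.88 ± 0.25) and VP1828, a putative pnuC gene at least 1.33-fold higher, whose log2 change turned to -0.32 (adjusted p = 0.13) with normexp. With normexp the median of all genes was -0.63. Other medians over 1.5 times smaller with normexp were 0.40 for phosphate uptake, 0.69 for type IV pili, 0.12 for iron acquisition, 0.17 for the polar flagellum, 0.68 for SOS and DNA repair, -1.75 for the TCA cycle and -1.38 for the capsule list. In iron acquisition 14 of 28 genes rose and 1 fell (median 0.97, adjusted p = 0.013, and adjusted p = 0.44 with an estimated correlation, slide medians 0.55, 0.93 and 1.52). The polar flagellum had 23 rises and 3 falls among 51 genes (median 0.76, adjusted p = 0.025, and adjusted p = 0.44 with an estimated correlation, slide medians 0.30, 0.91 and 0.95).

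Of the fixed genes, toxR (-1.36 ± 0.25), relA (-1.25 ± 0.20) and tdhA (-1.45 ± 0.33, uncertain as above) fell. On slides 1, 2 and 3 the values were -0.45, -1.40 and -1.75 for toxR, -0.67, -1.44 and -1.30 for relA and -0.40, -2.24 and -1.59 for tdhA. The others did not pass: the value was -0.83 ± 0.17 for rpoS, -0.10 ± 0.37 for opaR, 0.21 ± 0.37 for recA, -0.23 ± 0.15 for ftsZ and -0.43 ± 0.24 for tlh. Of these, rpoS missed only the 2-fold minimum (limma adjusted p = 9.0e-05). With no scaling the signs of toxR, relA, tdhA, opaR, ftsZ and tlh turned. In all, 1255 genes were higher and 1001 lower in VBNC than in early stationary cells (limma). Within slides 1, 2 and 3 the counts were 1113 and 910, 1296 and 1135, and 1330 and 1075, and they were 1246 and 1016 with slide as a block. The split moved to 1004 higher and 1231 lower with the array median, 1608 and 758 with the trimmed mean, 344 and 1189 with normexp and 3179 and 153 with no scaling. With quantile normalization these lists no longer passed: ribosomal proteins (-0.62 against -1.14, adjusted p = 0.085) and chaperones and proteases (-0.87 against -0.80, adjusted p = 0.10). The median of the ribosomal proteins was -0.56 with the deposited values. Other medians over 1.5 times apart from those above were -0.47 for chaperones and proteases with the trimmed mean and 0.497 for the polar flagellum with the array median. No scaling moved the median of all genes by 1.84. The lower lists then had medians of 0.69 for ribosomal proteins, -1.97 for ribosome hibernation, -1.11 for the ATP synthase, -1.24 for the TCA cycle, 0.75 for fatty acid degradation, 1.03 for chaperones and proteases, 0.71 for type III secretion system 2 and -0.29 for the capsule list. Medians of the higher lists were 3.47 for SOS and DNA repair, 2.59 for the polar flagellum, 3.52 for type IV pili, 2.81 for iron acquisition, 4.22 for phosphate uptake and 3.28 for the superintegron.

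**Figure D3:**
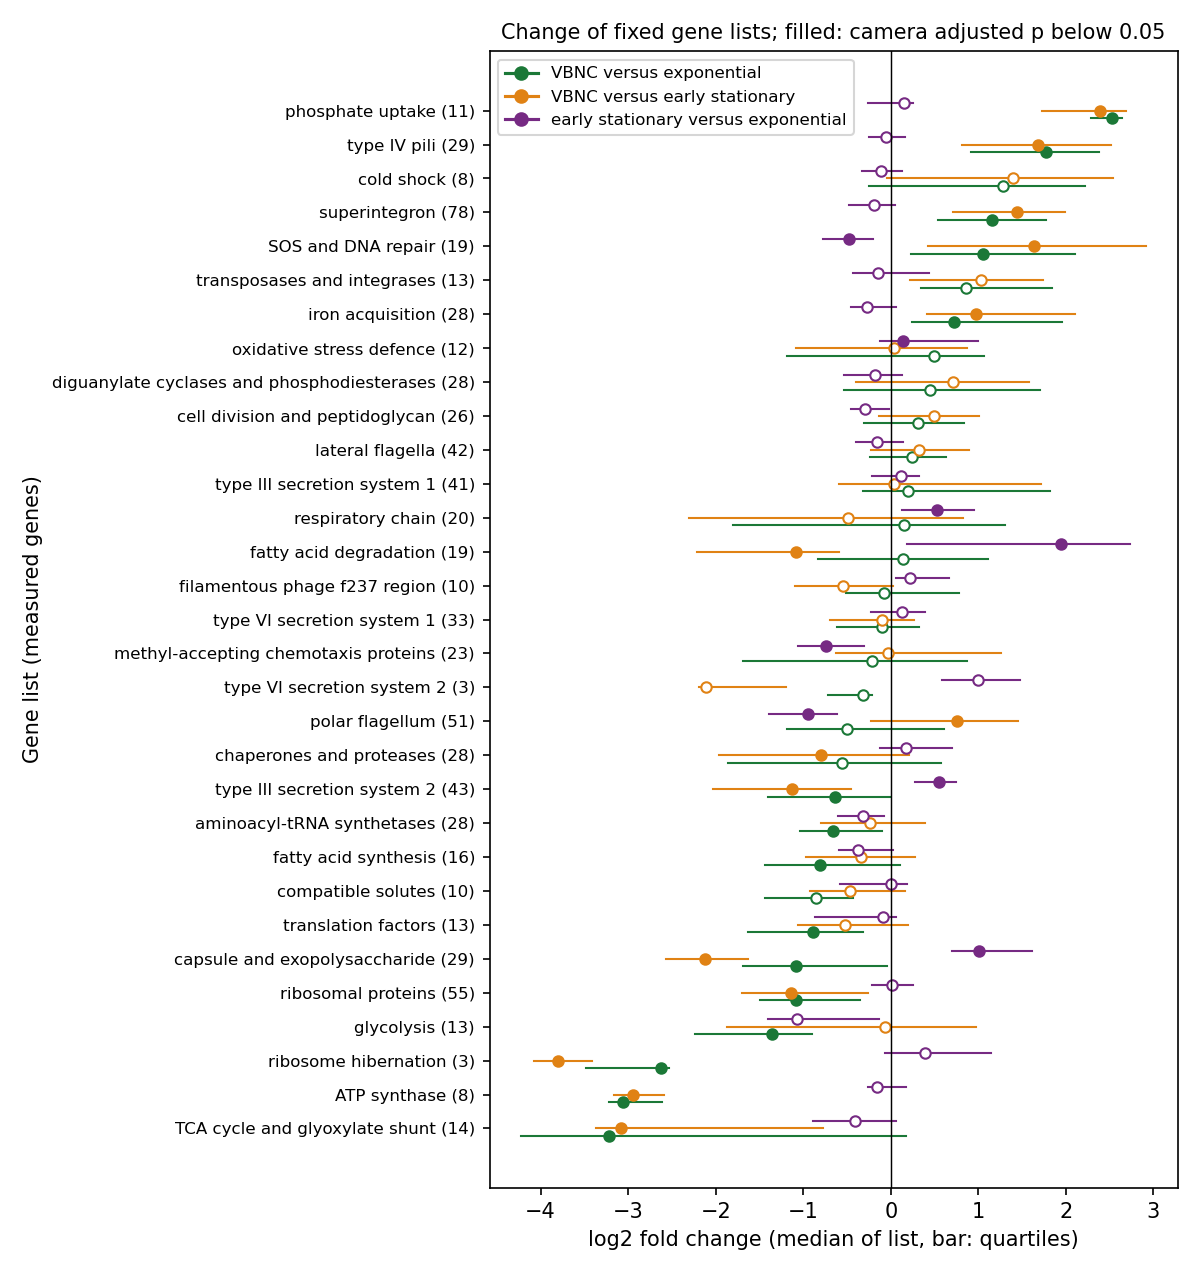
Median log2 fold change (x axis) of the 31 tested gene lists (y axis, measured genes in brackets) in the 3 comparisons, with bars from the lower to the upper quartile of the members. Filled points passed camera with the preset correlation; no list passed with an estimated correlation. The ATP synthase median lies at -3.05 and -2.95 in the VBNC comparisons and at -0.15 between the growth phases.

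Genes that differed from both growth phases in the same direction were counted next. This held for 929 genes higher and 712 lower in VBNC cells, while 17 passed in opposite directions. Both comparisons use the same VBNC arrays. Independent lists of these sizes would share 314 and 225 genes. In simulated groups with no difference but the observed spread between sets of arrays on a slide, added after the data were seen, at most 30 higher and 36 lower genes were shared in 100 runs. These runs drew each gene independently of the others, so genes that move together on a slide could share more. With the VBNC arrays of 1 slide set against all exponential arrays and those of another slide against all early stationary arrays, a check also added then, 681 to 874 higher and 499 to 695 lower genes were shared over the 6 such pairs of slides. The split between higher and lower depended on the scaling. It was 791 and 838 with the array median, 1212 and 507 with the trimmed mean, 295 and 487 with normexp and 1903 and 111 with no scaling. Named genes among the 929 and 712 included VP1890, recN, recO, pilP and VP0574 as rises, and VP0847, VP3075, citrate synthase and VP0223 as falls.

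The third comparison set the growth phases against each other. Fatty acid degradation rose in early stationary cells, with 12 of 19 genes up and 3 down (median 1.94, adjusted p = 3.7e-06, and adjusted p = 0.30 with an estimated correlation, slide medians 1.22, 2.89 and 1.65). A putative enoyl-CoA hydratase (VPA0624) changed by 4.41 ± 0.34 and a putative acyl-CoA dehydrogenase (VPA1121) by 3.79 ± 0.49, the latter well above background on 3 of 8 exponential arrays. The largest rise was in a putative acyl-CoA thiolase (VPA1123, chromosome 2, 1186125 to 1187303), 27.9-fold, at 3.53 ± 1.81 (SD, n = 8) against -1.27 ± 0.86 (SD, n = 8) (log2 change 4.80 ± 0.54, adjusted p = 1.6e-07). VPA1123 was not matched to the fatty acid degradation list. VPA0647 rose 27.6-fold, a putative fimbrial gene (VP2423) 24.9-fold with 2 of 8 exponential arrays well above background, and an agglutination protein gene (VP1631) 23.1-fold. On slides 1, 2 and 3 the log2 changes were 2.63, 5.92 and 6.13 for VPA0647 and 2.27, 5.40 and 6.17 for VP1631. Of the capsule and exopolysaccharide genes 15 of 29 rose and none fell (adjusted p = 1.2e-09, and adjusted p = 0.30 with an estimated correlation, slide medians 0.17, 1.14 and 2.05), including otnA (VP0220, 1.25 ± 0.28) and VP0228 (1.12 ± 0.23). On slide 1 the log2 values were 0.15 for otnA and 0.37 for VP0228. In type III secretion system 2, 5 of 43 rose and none fell (median 0.55, below 0 with no scaling; adjusted p = 3.7e-06, and adjusted p = 0.52 with an estimated correlation, slide medians 0.17, 0.98 and 0.69), with VPA1339 at 1.63 ± 0.28 and VPA1338 at 1.29 ± 0.25, and 0.73 and 0.59 on slide 1. The respiratory chain had 5 rises and 2 falls among 20 genes (adjusted p = 0.0081, and adjusted p = 0.45 with an estimated correlation, slide medians -0.15, 0.58 and 1.24), and its median was below 0 with no scaling. Rises included the cytochrome c oxidase genes VP2607 (3.45 ± 0.31) and VPA0536 (2.46 ± 0.32). In oxidative stress defence 2 of 12 rose and none fell (median 0.14, below 0 with no scaling; adjusted p = 0.040, and adjusted p = 0.57 with an estimated correlation, slide medians 0.32, 1.04 and 0.03), namely the Cu-Zn superoxide dismutase VPA1514 (1.97 ± 0.30) and the catalase/peroxidase VPA0768 (1.94 ± 0.21).

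Between the growth phases the lateral flagella did not pass (0 of 42 rose, 3 fell, median -0.15, adjusted p = 0.69, and adjusted p = 0.89 with an estimated correlation). Of 51 polar flagellum genes, 21 fell and none rose (median -0.95, adjusted p = 4.8e-12, and adjusted p = 0.093 with an estimated correlation, slide medians -1.05, -1.19 and -0.93), including flgF (VP0780, -2.29 ± 0.18) and flgG (VP0781, -2.17 ± 0.20). Of the methyl-accepting chemotaxis proteins 7 of 23 fell and 1 rose (median -0.74, above 0 with normexp; adjusted p = 0.011, and adjusted p = 0.50 with an estimated correlation, slide medians -0.74, -0.44 and -0.94), with VPA1182 at -2.11 ± 0.30 and VP0421 at -1.28 ± 0.23 (-0.65 on slide 2). SOS and DNA repair had 2 falls among 19 genes (adjusted p = 0.031, and adjusted p = 0.45 with an estimated correlation, slide medians -0.21, -1.003 and -0.71), lexA changing by -1.76 ± 0.28, with -0.46 on slide 1. The largest single falls were in orotate phosphoribosyltransferase (VP0178, 13.3-fold), maltodextrin phosphorylase (VPA1620, 13.3-fold) and 4-alpha-glucanotransferase (VPA1619, 8.97-fold). These rest on slides 2 and 3: on slide 1 the log2 changes were -1.12, -1.09 and -0.99, against -4.48 to -5.96 on the other slides. Threonine 3-dehydrogenase (VPA1509), not well above background on early stationary arrays, was at least 3.15-fold lower. The fixed genes rpoS (1.53 ± 0.17, adjusted p = 9.3e-08) and tdhA (1.45 ± 0.33, uncertain as above) rose. On slides 1, 2 and 3 the values were 1.35, 2.14 and 1.19 for rpoS and 0.62, 3.41 and 0.72 for tdhA. Values of the rest, none of which passed, were 0.45 ± 0.25 for toxR, -0.21 ± 0.37 for opaR, 0.12 ± 0.20 for relA, 0.00 ± 0.37 for recA, -0.39 ± 0.15 for ftsZ and -0.24 ± 0.24 for tlh. Of these, ftsZ missed only the 2-fold minimum (limma adjusted p = 0.040).

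Between the growth phases 354 genes were higher and 396 lower in early stationary than in exponential cells (limma). These counts were 228 and 386 within slide 1, 854 and 683 within slide 2, 637 and 898 within slide 3, and 370 and 402 with slide as a block. With 1 mean per slide and group they were 137 and 76. Of the 354 and 396 genes, 161 and 151 passed in the same direction within slide 1. On slide 2 331 and 303 of them did, and on slide 3 296 and 346. The split moved to 463 higher and 267 lower with the array median, 110 and 52 with normexp and 78 and 867 with no scaling. List medians that differed over 1.5 times with normexp were 0.74 for fatty acid degradation, 0.49 for the capsule list, 0.33 for the respiratory chain, -0.60 for the polar flagellum, -0.04 for SOS and DNA repair, 0.08 for chemotaxis proteins and 0.39 for oxidative stress defence. With the array median they were 0.31 for oxidative stress defence and -0.31 for SOS and DNA repair. No scaling moved the median of all genes by -0.78. Lower lists then had medians of -1.25 for SOS and DNA repair, -1.73 for the polar flagellum and -1.52 for chemotaxis proteins. Medians of the higher lists were -0.25 for the respiratory chain, 1.16 for fatty acid degradation, -0.63 for oxidative stress defence, -0.22 for type III secretion system 2 and 0.22 for the capsule list. With quantile normalization 1 list no longer passed, oxidative stress defence (0.18 against 0.14, adjusted p = 0.058).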

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

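Tests chosen only after the result was seen were the correlation of slide deviations, the background error that follows array brightness, the swap of arrays, the wrong labels, the mixing of RNA and the splits of whole sets of arrays. A sample was singled out where its gap to the nearest other array of its group, as a share of the group's range, exceeded Dixon's 95% critical value for 8 samples. This held in 3 of 210 sets of 8 arrays, while chance would single out about 1 in 20 if arrays were independent. Arrays of a group on a slide are not, and an extreme value with a like neighbour goes unseen. The low share therefore does not show that the arrays were free of outliers. For VP0223, exponential replicate 6 lay at -2.50 against -0.65 to 0.97 on the others, a share of 0.534. For mshD (VP2695) the same array lay at -1.34 against -0.86 to -0.46, a share of 0.553. For VP1665, exponential replicate 7 lay at -5.44 against -4.06 to -2.87, a share of 0.536.

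The first pattern weighed was that arrays of a group on a slide resembled each other more than arrays of that group on other slides. A slide effect common to the groups would make their slide deviations correlate, and the median correlation across genes over 9 pairs was 0.178, which argues against it as the whole cause. Brightness was tested with quantile normalization, after which differences across slides were 2.35 times those within slides (median of the groups). The ratio went from 1.48 to 2.35 in exponential, from 1.99 to 1.82 in early stationary and from 3.47 to 3.70 in VBNC cells. Quantile normalization does not restore signals near background on dim arrays, so this test does not exclude brightness. Separate cultures or RNA preparations for each slide stay open, since the labels speak of biological replicates but do not tie cultures or preparations to slides. No biological explanation was tested.

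The second pattern was the rise of the superintegron list in VBNC cells, which was much smaller with normexp, as were the rises of phosphate uptake, iron acquisition and type IV pili. With the trend on probe GC content removed, 89.7% of its genes were still higher than in exponential and 92.3% than in early stationary cells, which argues against GC content. With normexp on slide 1, where VBNC arrays were the dimmer ones, 94.9% of the list were higher than in early stationary cells. This lay above the 70% set beforehand as a bound against brighter arrays. But 69.9% of all genes were higher there too, and the list median was 0.35 against 0.22 for all genes, so this share cannot decide. Without normexp, 84.6% of the list lay above the median of all genes on slide 1. But a dimmer array has a lower 75th percentile subtracted, which lifts genes near background. The list was not set against equally dim genes, so this share cannot decide either. Brighter arrays, an error that follows brightness and a change in VBNC against early stationary cells therefore all stay open as hypotheses. Against exponential cells the shares were 85.9% with normexp and 56.4% without, and there brighter arrays, such an error and a change in VBNC cells cannot be told apart, since 75.3% of all genes passed the same bound, as seen after the result, and the second share is close to an even split.

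The third pattern was the nearness of the exponential arrays of slide 1 to early stationary arrays, since the 3 arrays correlated better on average with early stationary (0.913 to 0.916) than with exponential arrays of the other slides (0.879 to 0.881). The lower average came from slide 3: single correlations were 0.906 to 0.922 with exponential arrays of slide 2 and 0.823 to 0.887 with those of slide 3. The pattern may thus in part reflect the exponential arrays of slide 3. All 3 early stationary arrays of slide 1 also correlated better with early stationary arrays of the other slides (0.950 to 0.952 against 0.862 to 0.864), which argues against a swap with them. Early stationary cells under wrong labels were tested with the polar flagellum list, which had the smallest p between the growth phases. Its median change on slide 1 was -1.05 (quartiles -1.51 and -0.63), against at most -0.52 between early stationary sets. That p came from a fit that includes slide 1, so the list was chosen in part for differing there and cannot decide. The 1214 genes passing on slides 2 and 3 alone did not decide either, with medians in their direction of 0.44 and up to 0.33. Wrong labels therefore stay open. Mixed RNA would shrink all falls alike, whereas the glycolysis median on slide 1 was -13.7% of its value on slides 2 and 3 and the polar flagellum median 99.6%. The choice of the polar flagellum list limits this test in the same way, and both lists were picked after the result was seen. It cannot decide, and mixed RNA stays open. A culture at another point of growth, or another sample outside this set, stays open as untested, since the labels give one culture time for all exponential samples.

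Whether arrays grouped by chance give such results was examined with 100 splits per comparison, the real one included. The real split passed 2133 genes for VBNC against exponential, 2256 against early stationary and 750 between the growth phases, and the highest of the other splits passed 31, 257 and 576; only 1 split in each case, the real one, reached its count. This excludes chance only for arrays taken as independent, which those of a group on a slide are not. With whole sets of arrays on a slide, in place of single arrays, only 10 splits exist, too few for a share under 0.05. With 1 mean per set the real counts were 1787, 1916 and 213 and the highest others 0, 0 and 5, with 1 split as large in each case. For genes passing against both phases the real count was 1641 and the highest other 0, with 1 split of single arrays as large. For the number of gene lists past the test, chance is not excluded. The real counts were 15, 14 and 8, the highest others 16, 16 and 17, and 7, 19 and 54 splits gave as many lists. Random splits passed 7 to 8 lists at the median, which points to a structure of the arrays that the preset correlation leaves out. List medians were split in the same way, by single arrays: for all lists past the test in both VBNC comparisons 1 split, the real one, gave a median as far from 0. Between the growth phases up to 62 splits did, for oxidative stress defence, and 5 for the respiratory chain. In both VBNC comparisons only the real split gave such a median for some lists that did not pass as well, among them cold shock and the transposases and integrases. The splits of medians therefore do not set the passing lists apart, and they too treat the arrays as independent.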

How the results depend on the processing

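Tests chosen after seeing the data were the means per slide, the random block for sets on a slide and the fits without VBNC replicates 1 and 2, exponential replicate 6 or exponential replicate 2. Counts of passing genes stayed within 1.5 times their reported values with quantile normalization, the array median, the trimmed mean, the deposited values, no filter, other probe summaries, marked spots kept, slide as a block, only the groups compared, and eBayes with trend. Higher and lower counts that moved further are given here; causes were not tested unless the setting itself changes the threshold or the number of genes or arrays. They were 1994 and 276 (VBNC against exponential), 3179 and 153 (VBNC against early stationary), 78 and 867 (growth phases) and 1903 and 111 (against both phases) with no scaling, 628 and 537 (VBNC against exponential), 730 and 556 (VBNC against early stationary), 104 and 42 (growth phases) and 518 and 354 (against both phases) with treat against a 2-fold change, and 465 and 379 (VBNC against exponential), 531 and 403 (VBNC against early stationary), 115 and 40 (growth phases) and 381 and 240 (against both phases) at 4-fold. With normexp they were 393 and 613, 344 higher against early stationary, 110 and 52 between the growth phases and 295 higher against both. The strict filter, which tests 2108 genes, gave 401 and 624 (VBNC against exponential), 445 and 622 (VBNC against early stationary), 166 and 159 (growth phases) and 321 higher against both. With no fold minimum 549 and 935 genes passed between the growth phases. Within slides, the growth phases gave 228 higher on slide 1, 854 and 683 on slide 2, and 637 and 898 on slide 3. With 3 means per group they gave 137 and 76, and 235 lower with the random block (consensus correlation 0.775). VBNC against exponential gave 967 and 820 genes with 3 means per group, and VBNC against early stationary 1092 and 824. In simulated VBNC and exponential groups with no difference but the observed spread between sets on a slide (4494 genes, drawn independently of each other), a mean of 172 genes passed with 8 arrays per group and 0 with 3 means. Without VBNC replicates 1 and 2, counts were 1132 and 1070 (VBNC against exponential), 1291 and 1051 (VBNC against early stationary), 356 and 396 (growth phases) and 955 and 760 (against both phases); without exponential replicate 6 they were 1149 and 981 (VBNC against exponential), 1255 and 1001 (VBNC against early stationary), 361 and 365 (growth phases) and 934 and 707 (against both phases), and without exponential replicate 2 1211 and 984 (VBNC against exponential), 1256 and 1004 (VBNC against early stationary), 419 and 400 (growth phases) and 965 and 687 (against both phases).

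Against the reported values, the median log2 change of all genes shifted by 1.06, 1.84 and -0.78 in the order of comparisons with no scaling, and by -0.43, -0.78 and 0.37 with normexp. It shifted by 0.31 and 0.33 in the VBNC comparisons with the trimmed mean, by -0.26 for VBNC against early stationary and 0.16 between the growth phases with the array median, and by -0.13 and -0.11 for VBNC against early stationary with quantile normalization and the deposited values. Changes are relative to these. No gene list passed with an estimated correlation (0 higher and 0 lower in every comparison; camera with the preset correlation passed 5 and 10, 6 and 8, and 5 and 3). With quantile normalization 6 lists were lower for VBNC against exponential and 6 against early stationary cells. With the array median 9 and 7 were lower in these comparisons, and 4 were higher between the growth phases. With 1 mean per slide and group 9 were lower against exponential cells, and without exponential replicate 2 4 were higher between the growth phases. Without VBNC replicates 1 and 2, 7 were lower against exponential cells, those of translation factors, glycolysis and fatty acid synthesis losing the call. Of 744 list tests, run under 8 of the alternatives, 53 lost and 8 gained the call, and none reversed. They were not run with no scaling, the trimmed mean, normexp, the deposited values or within slides, where some list medians changed sign. Of 2432 values of named genes under the alternatives, 2305 kept direction and side of the threshold or had no called direction, 93 lost and 24 gained the call and 10 turned. For VBNC against early stationary with no scaling, these were toxR 0.48, opaR 1.73, relA 0.58, ftsZ 1.61, tlh 1.41 and tdhA 0.39, and VP1828 -0.32 with normexp. Within slides, opaR was 1.19 for VBNC against early stationary on slide 1, and opaR 1.15 and recA -1.20 between the growth phases on slide 2. Of the 93 lost calls of named genes, 17 came at 4-fold, 17 with normexp, 14 with no scaling and 13 within slide 1. A further 12 came with treat and 7 with 1 mean per slide and group.

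With the replicate number as a block the counts were 1128 and 1010 (VBNC against exponential), 1260 and 1007 (VBNC against early stationary), 362 and 395 (growth phases) and 931 and 716 (against both phases), and 4 in place of 5 lists were higher between the growth phases. The numbers did not pair the arrays by the rule that every same-numbered pair correlates above 0.1 in its deviations from the group means: this held for 6 of 8 pairs of exponential and early stationary arrays, 6 of exponential and VBNC arrays and 2 of early stationary and VBNC arrays. The best match was the own number for 2, 1 and 1 of them. Signal over background limits dim genes: on exponential replicate 6 44.6% of probes were well above background.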

Other observations

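Several lists did not pass in any comparison, though some of their members did. In the cold shock list, 5 of 8 genes rose and 1 fell in VBNC against exponential cells (adjusted p = 0.095, and adjusted p = 0.46 with an estimated correlation), with the same counts against early stationary cells (adjusted p = 0.15). Named after their values were seen, the cspA gene VP1889, which lies next to VP1890, changed by 4.63 ± 0.25 and 5.05 ± 0.25 (limma adjusted p = 8.3e-15 and 1.5e-15). A second cspA gene, VPA1289, changed by 3.63 ± 0.44 and 3.28 ± 0.44, while cspD (VP1012) fell, with -1.66 ± 0.36 and -3.43 ± 0.36. CspA proteins are known as RNA chaperones of the cold response. In the list of cyclic di-GMP enzymes (diguanylate cyclases and phosphodiesterases, 28 genes) the numbers that rose and fell were 9 and 5 against exponential, 12 and 5 against early stationary cells, and 1 and 2 between the growth phases. Rises and falls in type III secretion system 1 (41 genes) were 14 and 3 against exponential, 13 and 5 against early stationary cells, and 2 and 1 between the growth phases. They were 5 and 3 against exponential, 7 and 3 against early stationary cells, and 0 and 0 between the growth phases in cell division and peptidoglycan (26 genes), and 5 and 4 against exponential, 10 and 1 against early stationary cells, and 0 and 3 between the growth phases in the lateral flagella (42 genes).

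For the remaining lists the counts of rises and falls were 3 and 4 against exponential, 2 and 6 against early stationary cells, and 0 and 0 between the growth phases in type VI secretion system 1 (33 genes), and 0 and 1 against exponential, 0 and 2 against early stationary cells, and 1 and 0 between the growth phases in type VI secretion system 2 (3 of 23 genes measured, the others lying in the region described last). The transposases and integrases (13 genes) had 6 and 1 against exponential, 7 and 1 against early stationary cells, and 1 and 0 between the growth phases. Compatible solute genes (10) had 1 and 4 against exponential, 1 and 2 against early stationary cells, and 0 and 2 between the growth phases, and the filamentous phage f237 region (10 genes) had 2 and 2 against exponential, 2 and 4 against early stationary cells, and 2 and 0 between the growth phases. For lists that passed only in another comparison the counts were as follows. Against exponential cells, rises and falls in VBNC cells were 3 and 4 in oxidative stress defence, 7 and 10 in chaperones and proteases, 9 and 17 in the polar flagellum, 5 and 4 in fatty acid degradation and 5 and 8 in chemotaxis proteins. Against early stationary cells they were 1 and 4 in translation factors, 5 and 5 in aminoacyl-tRNA synthetases, 2 and 3 in fatty acid synthesis, 6 and 3 in chemotaxis proteins and 2 and 3 in oxidative stress defence. Between the growth phases they were 0 and 7 in glycolysis, 2 and 1 in the TCA cycle and glyoxylate shunt, 0 and 1 in the ATP synthase, 0 and 1 in ribosomal proteins, 1 and 3 in translation factors, 0 and 4 in aminoacyl-tRNA synthetases and 1 and 0 in ribosome hibernation. They were 0 and 1 in fatty acid synthesis, 3 and 2 in chaperones and proteases, 0 and 3 in iron acquisition, 0 and 0 in phosphate uptake, 1 and 0 in type IV pili and 1 and 3 in the superintegron.

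The shares of genes that were higher were also taken by chromosome. In VBNC against exponential cells 31.9% of tested chromosome 2 genes and 21.5% of chromosome 1 genes were higher. Within slide 1 alone, 27.4% and 20.2% were higher. Against early stationary cells 32.7% and 25.4% were higher. The odds ratio of being higher on chromosome 2 was 1.72 and 1.42 in these comparisons and 1.87 in early stationary against exponential cells, so it was not particular to VBNC cells. Genes that were higher in VBNC cells had been dim in exponential cells, with a median level of -2.80 against -0.09 for those that were lower and -1.83 for all genes. The exponential level is itself subtracted in the change that sorts these genes, so part of this difference is built in. Products named hypothetical made up 43.2% of the higher, 24.8% of the lower and 36.2% of all tested genes. Genes are not independent of their neighbours, so these shares are given without a test.

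A region of chromosome 2 gave almost no signal in any state. Of 134 genes from VPA0910 to VPA1043 (945575 to 1102916), 133 failed the detection filter, which is 40.8% of all genes it left out, and 20 of them belong to type VI secretion system 2. On exponential replicate 2 68.3% of the region's probes were well above background, with a median 2.88 log2 units above the negative controls. On the other 23 arrays 0.240% to 11.3% were. The median lay 0.83 log2 units above the negative controls on exponential replicate 8 and -0.02 to 0.22 on the remaining arrays. Whether the cultured cells lacked these genes or did not transcribe them was not tested, nor was the source of the signal on exponential replicate 2. Without that array 1211 genes were higher and 984 lower in VBNC than in exponential cells.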
